A study of Homo sapiens with 12 samples.

How the data were processed

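Gene expression was measured by RNA sequencing in 2 established human diffuse large B cell lymphoma lines, SU-DHL-8 and Farage. Each line was given vehicle (control) or morusinol for 12 h, with 3 replicates in each of the 4 groups and 12 libraries in all. Morusinol is a prenylated flavonoid of mulberry (Morus) root bark. The dose is not given in the sources used here, and neither is whether the replicates were separate cultures. Libraries were made from total RNA with a SMARTer mRNA-seq kit.

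The authors deposited a single table of FPKM (fragments scaled by gene length and by the depth of the library), with 1 column per library, and no counts were used. The aligner, the counting program, the annotation release and the strand of counting are not given in the sources used here. The labels list only mouse genome builds (GRCm38 and mm10), yet all 61466 gene identifiers in the table are human Ensembl identifiers, and 58297 of them (94.8%) match GENCODE release 29 on the human build GRCh38. Positions and gene types are therefore those of GENCODE release 29. The table was not cleared of genes without signal, since 19053 genes were at 0 in all libraries. The 13 mitochondrially encoded genes were among these, so they were removed or not counted. Columns were assigned to groups by their names: those marked mor are morusinol, and those marked n were taken as control because the labels leave no other group for them. No pair of libraries held identical values, and 432 genes repeated the values of another gene in all libraries.

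Depth was estimated from the table itself, because a value times the exon length of its gene falls on steps set by the library's number of fragments. With a tolerance of 0.02 fragments, 50.9% to 52.9% of the values under 50 fragments fell on a whole number of fragments. Counting steps of 0.5 as well brought this to 72.8% to 76.7%. The estimated number of fragments assigned to genes was 15.2, 14.2 and 14.8 M (mega, a unit of depth) in the SU-DHL-8 control libraries and 11.3, 6.05 and 15.0 M in the SU-DHL-8 morusinol libraries. It was 19.0, 18.6 and 16.6 M in the Farage control libraries and 12.7, 9.37 and 10.7 M in the Farage morusinol libraries. These are estimates, so no counting intervals are given, and the precision of each value is shown by the spread of the 3 libraries.

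Values were used with the scaling of the authors' table. Genes with an FPKM of at least 1 in at least 3 libraries were kept (17574 genes), values were transformed to log2(FPKM + 1), and limma 3.58.1 in R 4.3.3 was fitted to all 12 libraries with 1 mean per group. The empirical Bayes step used an intensity trend and a robust prior. Contrasts were morusinol minus control in each line, the Farage response minus the SU-DHL-8 response, and Farage control minus SU-DHL-8 control. A gene was called when its Benjamini-Hochberg adjusted p, over the 17574 genes, was under 0.05. All tests were two-sided. Tables were prepared and plots drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

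A total of 35 gene lists with 687 genes were fixed before the data were examined, covering sterol and lipid metabolism, stress responses, the cell cycle, energy metabolism, signalling, B cell states and markers of other cell types. The table held 686 of these genes, and 31 lists had at least 5 tested members. Lists were tested with camera (limma) at a preset correlation between genes of 0.01 and again with an estimated correlation, and their p-values were adjusted over the 31 lists. The test named fry (limma) was run beside them; it asks whether the members of a list move, on balance, in 1 direction, without comparing them with other genes. It called 31 lists in SU-DHL-8, 29 in Farage, 27 for the difference of the responses and 27 for the controls. With the preset correlation camera also called lists when the libraries of a line were regrouped, and with the estimated correlation it called none. Calls that hold with the estimated correlation are given first. The regroupings keep a part of the treatment effect, so they do not show that calls lost with the estimated correlation are false. Nor do they show that calls kept with it are true. A regrouping leaves treatment effect in the residuals from which that correlation is estimated. Counts of called members are over all genes tested, and counts adjusted over the list alone are given beside them for the lists described in most detail.

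Genes to be named were chosen by a rule written before the data were examined. It took genes with a symbol, a mean FPKM of at least 5 in the higher group and no overlap between the 3 treated and 3 control values. Of these, the 10 largest rises and the 10 largest falls per line, the 10 largest differences between the lines and the 5 largest control differences in each direction could be named. Up to 4 members of each list called in either line were added by their p ranks over both lines, as were all members of the lists on cholesterol synthesis and SREBP2 regulation and 6 markers of B lymphocytes.

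The fit was tested on simulated data with the depth and abundance of these libraries, in which 200 genes were changed in 1 line. The changed genes were drawn from those with an FPKM of at least 5 in the controls of both lines. Every gene was given the same spread beyond counting (dispersion 0.0017), taken from genes with many fragments. Recovery of genes of lower level was therefore not tested, and the false shares hold only for 200 changed genes with that spread. In the SU-DHL-8 comparison (16652 genes) 91.0% of the genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold were recovered. In the Farage comparison (16680 genes) the shares were 97.0%, 98.5% and 100%. Of the 209 and 216 calls, 7.66% and 8.80% were false, above the nominal share of 5%. For the difference of the responses, 70.1% (change in SU-DHL-8) and 77.6% (change in Farage) of the genes changed 1.5-fold were recovered. Of the calls for this difference, 7.73% and 8.0% were false. The line left without a change gave 3 and 1 false calls. A list of 20 changed genes was called in its own line, and none of 30 lists of random genes was. Simulated genes varied independently, whereas real list members can be correlated (estimated at 0.53 for cytosolic ribosomal proteins). The simulation therefore does not show how often such lists are falsely called.

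Alternatives fixed before the data were examined were a pseudocount of 0.1 or 3, no filter on low values or an FPKM of at least 5, rescaling to TPM, median-of-ratios scaling, quantile normalization, a fit to the compared libraries alone, no trend or robust prior, a block for the replicate number, an adjusted p under 0.01, a log2 fold change of at least 1, and each library left out in turn. Chosen after seeing the data were precision weights from the estimated fragments (voom in limma), scaling to the sum over protein-coding genes, and protein-coding genes alone.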

Results

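The data are the FPKM of 12 libraries, 3 from each of SU-DHL-8 control, SU-DHL-8 morusinol, Farage control and Farage morusinol, all taken at 12 h. Both lines are established lymphoma lines derived from mature B cells. Estimated depth was 6.05 to 15.2 M (mega) fragments in SU-DHL-8 and 9.37 to 19.0 M in Farage. Over the 17574 genes tested, log2 values of libraries of the same group correlated across genes with Pearson r of 0.964 to 0.980, treated and control libraries of the same line with 0.922 to 0.937, and libraries of different lines with 0.726 to 0.796. Because the replicates are not said to be separate cultures, the p-values below measure only the spread between these libraries. Values are means ± SD in FPKM and log2 fold changes of FPKM + 1 ± SE, with n = 3 libraries per group throughout. The 13 mitochondrially encoded genes were at 0 in all libraries, so they could not be tested.

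Most markers of other cell types were low. Of 14 myeloid markers LYZ had the highest group mean, 1.37 FPKM in SU-DHL-8 controls, and was at 0 in Farage. Of 14 fibroblast, endothelial and epithelial markers it was PDGFRB, at 1.07 FPKM in Farage morusinol and 0.273 in Farage controls. Of the 14 T and NK cell markers, TRAC, a T cell receptor constant region, had group means of 2.30 and 1.09 FPKM in SU-DHL-8 control and morusinol and 47.1 FPKM in Farage morusinol, and reached 75.6 FPKM in a Farage control library. The cytotoxic cell gene PRF1 was at 4.05 and 3.73 FPKM in Farage control and morusinol and at 0 in SU-DHL-8, and NKG7 had group means of 0.455 to 1.95 FPKM. CD3D, CD3E and CD3G, which code for the receptor's partner chains, had group means of at most 0.0425 FPKM (CD3E in Farage morusinol). The 6 markers of B lymphocytes were present in every group.

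The first comparison asks what morusinol changed in SU-DHL-8 within 12 h. All 20 tested chaperone and unfolded protein response genes of the endoplasmic reticulum (ER) rose, while 17 of 21 genes of cholesterol synthesis and all 32 genes of the G1/S and DNA replication list fell (adjusted p = 0.00271, 0.00405 and 0.00405 in camera with an estimated correlation). HSPA5 (BiP, the main chaperone of the ER) rose from 73.0 ± 1.13 to 375 ± 1.5 FPKM (log2 fold change 2.34 ± 0.0347, adjusted p = 5.0e-11), and PPP1R15A (GADD34, which directs the dephosphorylation of eIF2alpha) rose from 14.1 ± 1.66 to 154 ± 6.88 FPKM (3.36 ± 0.0866). HMGCS1 (the cytosolic HMG-CoA synthase of the mevalonate pathway) fell from 15.8 ± 1.32 to 5.49 ± 0.288 FPKM (-1.37 ± 0.0687), and MCM4 (a subunit of the replicative helicase) fell from 90.1 ± 1.16 to 21.1 ± 0.548 FPKM (-2.04 ± 0.0458). In all, 8216 of 17574 genes (46.8%) were called, 4414 higher and 3802 lower. Of these, 779 rose and 503 fell by at least 2-fold, and the median absolute log2 fold change of called genes was 0.54.

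Among the largest rises allowed by the rule for named genes, OLAH (ENSG00000152463, a thioesterase that releases medium-chain fatty acids) went from 0.372 ± 0.0607 to 28.1 ± 1.20 FPKM (log2 fold change 4.41 ± 0.0743), TREML2 (ENSG00000112195) from 1.02 ± 0.129 to 26.7 ± 1.24 FPKM (3.78 ± 0.0803) and PLEK (pleckstrin, ENSG00000115956, a substrate of protein kinase C) from 5.2 ± 0.502 to 83.8 ± 1.45 FPKM (3.78 ± 0.0530). INHBE, the inhibin beta E chain, rose by 3.37 ± 0.110 on the log2 scale. MMP8 (neutrophil collagenase, on chromosome 11 at 102711795 to 102727050) was listed at 0 in all 3 SU-DHL-8 control libraries and at 9.71, 8.65 and 9.04 FPKM after morusinol. The largest falls included VPREB3 (part of the surrogate light chain family of B cells), from 112 ± 7.39 to 6.20 ± 3.29 FPKM (-4.10 ± 0.335), and MYBPH (a myosin binding protein), from 18.4 ± 0.659 to 0.399 ± 0.103 FPKM (-3.80 ± 0.0828). SPIB, an ETS transcription factor of B cells, fell from 13.1 ± 0.939 to 0.573 ± 0.0215 FPKM (-3.16 ± 0.0730) and ATP2A3, a calcium pump of the ER, from 67.6 ± 3.51 to 9.71 ± 0.331 FPKM (-2.68 ± 0.0687). RGS19, a regulator of G protein signalling, fell by 3.28 ± 0.144 on the log2 scale. MIR6813 (chromosome 20, 64076955 to 64077010) lies within RGS19 (64073181 to 64079988) on the same strand and fell by 3.0 ± 0.621, so its fragments cannot be assigned to the microRNA with certainty.

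Stress lists moved in both directions in SU-DHL-8. All 20 tested members of the list on ER chaperones and the unfolded protein response rose (median log2 fold change 1.65, camera adjusted p = 4.5e-17, adjusted p = 0.00271 with an estimated correlation), among them HERPUD1 (ER-associated degradation, 2.31 ± 0.0284) and XBP1 (a transcription factor of the unfolded protein response, 1.95 ± 0.0453). Of 24 amino acid stress targets of the transcription factor ATF4, 19 rose and 2 fell (median 0.70, adjusted p = 0.0211 with an estimated correlation), including ATF3 (2.90 ± 0.0551), the stress transcription factor CHOP, DDIT3 (2.40 ± 0.0754), and TRIB3 (2.02 ± 0.0672). DDIT3 overlaps MARS1 on the opposite strand. The p53 target list also rose (13 higher and 5 lower of 21, median 0.59, adjusted p = 0.0336 with an estimated correlation), with the death receptor TNFRSF10B at 1.83 ± 0.0467 and the BH3-only gene BBC3 (PUMA) at 1.74 ± 0.0983. It shares genes with the ATF4 list, among them SESN2. The heat shock list fell, with 15 of 18 members lower and none higher (median -1.10, adjusted p = 0.00405 with an estimated correlation), and the chaperones HSPA8 and HSP90AA1 at -2.11 ± 0.0418 and -1.84 ± 0.0396. In the list of NRF2 targets, which respond to oxidative stress, 14 of 19 fell and 3 rose (median -0.45, adjusted p = 0.0336 with an estimated correlation); the peroxidase PRDX1 fell by 1.53 ± 0.0695, while the cystine transporter SLC7A11, also an ATF4 target, rose by 1.57.

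Sterol and growth lists fell in SU-DHL-8. Of the 21 genes of cholesterol synthesis 17 fell, 4 were not called and none rose (median -0.76, camera adjusted p = 2.0e-09, adjusted p = 0.00405 with an estimated correlation); adjusted over the list alone, 0 higher and 18 lower. SQLE (squalene epoxidase) changed by -0.98 ± 0.0322 and LSS (lanosterol synthase) by -0.80 ± 0.0632. All 32 genes of the G1/S and DNA replication list fell (median -1.22, adjusted p = 0.00405 with an estimated correlation), PCNA, the sliding clamp of DNA polymerase, by 1.64 ± 0.0487. The G2/M and mitosis list fell (24 lower and 1 higher of 29, median -0.62, adjusted p = 0.00880 with an estimated correlation), as did MYC and nucleolar targets (22 lower and 1 higher of 25, median -0.55, adjusted p = 0.00694). The mitotic cyclin gene CCNB1 changed by -1.44 ± 0.0430. Nuclear-encoded oxidative phosphorylation (24 lower and 2 higher of 26, median -0.55, adjusted p = 0.0377 with an estimated correlation) and the proteasome (all 18 lower, median -0.60, adjusted p = 0.0213) fell too, with ATP5MC1, a subunit of the ATP synthase, at -1.44 ± 0.0747. Adjusted over each list alone, the counts were 0 higher and 32 lower for G1/S and 1 higher and 26 lower for G2/M.

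B cell lists parted in SU-DHL-8. The plasma cell differentiation list rose, with 10 of 12 members higher and none lower (median 0.94, adjusted p = 0.00694 with an estimated correlation), among them IRF4, a transcription factor of plasma cells (1.79 ± 0.0395), and CD38 (1.03 ± 0.0620); XBP1 is a member of this list and of the ER list. NF-kappaB targets rose (15 higher and none lower of 25, median 0.37, adjusted p = 0.0277 with an estimated correlation), with the NF-kappaB subunit gene RELB at 2.22 ± 0.0761. B cell receptor signalling fell (12 lower and 4 higher of 22, median -0.34, adjusted p = 0.0461 with an estimated correlation), the exchange factor VAV1 by 1.29 ± 0.0797. The AMPK and mTOR pathway list rose (11 higher and 1 lower of 17, median 0.25, adjusted p = 0.0336 with an estimated correlation). It shares SESN2 and DDIT4 with the ATF4 list and holds genes that act for and against mTOR. Of the B lymphocyte markers, CD79A, a signalling chain of the B cell receptor, fell from 175 ± 5.13 to 43.0 ± 2.88 FPKM (-2.0 ± 0.0645), and MS4A1 (CD20) and CD22 changed by -0.55 ± 0.0853 and -1.25 ± 0.0727. CD79B and PAX5 rose by 0.35 ± 0.102 and 0.18 ± 0.0617.

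For a further 7 lists in SU-DHL-8 camera's call with the preset correlation was lost with the estimated correlation. Cytosolic ribosomal proteins had 24 of 25 members higher, RPL3 by 0.61 (median 0.34, adjusted p = 0.232 with an estimated correlation). Glycolysis and hypoxia genes had 16 of 25 lower and 3 higher (median -0.51, adjusted p = 0.0641), with lactate dehydrogenase LDHA at -2.11 ± 0.0370 and pyruvate kinase PKM at -1.66 ± 0.0476. Fatty acid synthesis had 7 of 10 lower and 1 higher (-0.32, adjusted p = 0.0663), with the desaturase SCD at -2.29 ± 0.0408 and fatty acid synthase FASN at -1.26 ± 0.0614. Autophagy and lysosome genes had 15 of 26 higher and 4 lower (0.34, adjusted p = 0.0688), with the autophagosome gene MAP1LC3B at 2.04 ± 0.0455. Immediate early genes had 15 of 25 higher and 2 lower (0.40, adjusted p = 0.0663), JUN at 2.10 ± 0.0889. Antigen presentation had 12 of 21 higher and 3 lower (0.21, adjusted p = 0.220). Replication-dependent histones had 9 of 16 higher and 2 lower (0.27, adjusted p = 0.471), and their call at the preset correlation was also lost in 4 of the 6 fits that left out a library (highest adjusted p = 0.0679).

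The remaining 9 lists were not called in SU-DHL-8. SREBP2 regulation and sterol uptake had a median of -0.29 (camera adjusted p = 0.0844), although INSIG1 (a sterol-sensing ER protein) fell by 0.79 ± 0.0499. SREBF2 itself, which codes for the transcription factor SREBP2, was at -0.08 ± 0.0471 (adjusted p = 0.215). The medians of the others were 0.23 for LXR targets and sterol efflux (adjusted p = 0.137), -0.22 for fatty acid oxidation (0.126), 0.11 for metallothioneins (0.215), -0.00 for xenobiotic receptor targets (0.378), 0.07 for apoptosis regulators (0.484), -0.41 for cell cycle inhibitors and G1 regulators (0.202), 0.10 for interferon-stimulated genes (0.481) and -0.01 for germinal centre B cell genes (0.310). In total, camera called 22 of 31 lists with the preset correlation (11 up, 11 down) and 15 with the estimated correlation (6 up, 9 down). The balance of rising and falling genes in this line depends on scaling: the share of called genes that were higher was 53.7% as deposited, 43.9% after rescaling to TPM and 60.0% after scaling to protein-coding genes.

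**Figure D1:**
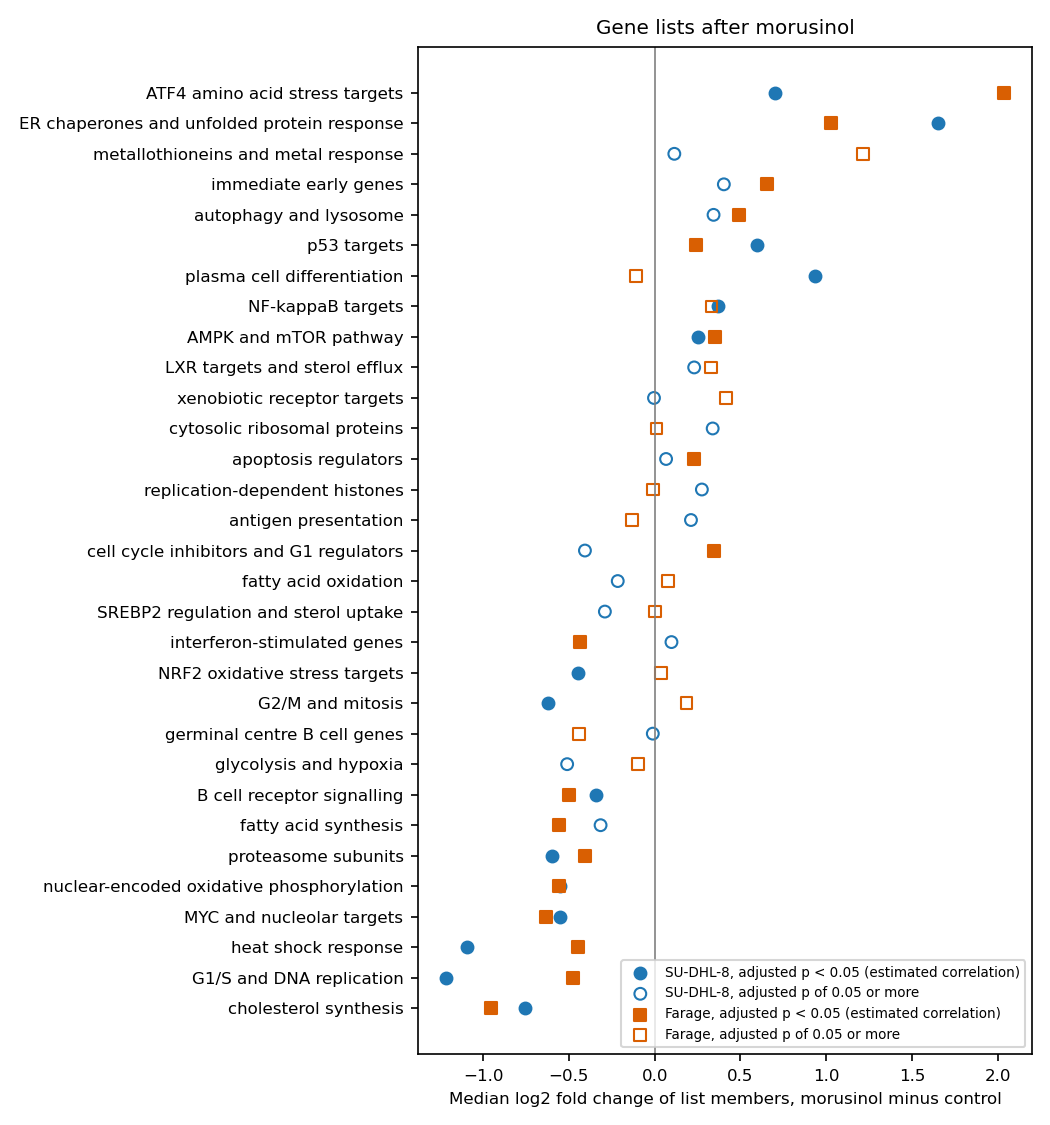
Median log2 fold change (morusinol minus control, on FPKM + 1) of the tested members of each of 31 gene lists in SU-DHL-8 (circles) and Farage (squares), with lists in order of their mean over the lines. Filled symbols passed an adjusted p of 0.05 in camera with an estimated correlation, which 15 lists did in SU-DHL-8 and 17 in Farage; the ATF4 targets lie at 0.70 and 2.04 and cholesterol synthesis at -0.76 and -0.95.

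The second comparison asks the same of Farage. Amino acid stress targets of ATF4 had the highest median of the 31 lists, with 23 of 24 higher (adjusted p = 0.00265 with an estimated correlation). ATF3 (a stress transcription factor, ENSG00000162772) went from 1.11 ± 0.160 to 25.9 ± 0.600 FPKM (log2 fold change 3.68 ± 0.0551, adjusted p = 1.5e-10), SESN2 (a sensor that restrains mTORC1) from 6.69 ± 0.0661 to 90.4 ± 4.13 FPKM (3.57 ± 0.0756), and CHAC1 (which degrades glutathione) from 4.30 ± 0.652 to 55.3 ± 3.83 FPKM (3.41 ± 0.112). ER chaperones rose as well, HSPA5 from 112 ± 5.12 to 283 ± 4.05 FPKM (1.33 ± 0.0347), and genes of cholesterol synthesis fell, HMGCS1 from 54.3 ± 2.44 to 10.7 ± 0.805 FPKM (-2.24 ± 0.0687). In all, 7567 of 17574 genes (43.1%) were called, 3848 higher and 3719 lower. Of these, 438 rose and 450 fell by at least 2-fold, and the median absolute log2 fold change of called genes was 0.49.

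Other large rises in Farage were CTH (cystathionine gamma-lyase, 3.28 ± 0.0552), STC2 (the secreted glycoprotein stanniocalcin 2, 3.21 ± 0.0852), DDIT3 (3.13 ± 0.0754), GPT2 (mitochondrial alanine aminotransferase, 2.90 ± 0.0498) and TSC22D3 (GILZ, 2.79 ± 0.0615). The falls included VPREB3 (-3.04 ± 0.335), the perforin-like gene MPEG1 (from 59.1 ± 0.717 to 9.0 ± 0.0662 FPKM, -2.59 ± 0.0417), JCHAIN (the joining chain of IgM and IgA, -2.53 ± 0.155) and the chemokine CCL4 (-2.43 ± 0.124). Beta-actin, ACTB (chromosome 7, 5527147 to 5563784), fell from 2376 ± 91.3 to 435 ± 6.28 FPKM (-2.45 ± 0.0440), and it fell by 2.28 ± 0.0440 in SU-DHL-8. The pseudogene NAPSB fell by 2.90 ± 0.123 and overlaps NR1H2 on the opposite strand, and MPEG1 overlaps DTX4 in the same manner. TRAJ4, a joining segment of the T cell receptor alpha locus, was at 11.7, 15.4 and 15.8 FPKM in the Farage control libraries. After morusinol it was at 5.02 FPKM in 1 library and listed at 0 in the other 2.

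Among stress lists in Farage, 23 of 24 ATF4 targets rose and 1 fell (median 2.04, camera adjusted p = 1.0e-22, adjusted p = 0.00265 with an estimated correlation), and 19 of 20 ER chaperone and unfolded protein response genes rose and 1 fell (median 1.03, adjusted p = 0.00265). XBP1 rose by 2.49 and HERPUD1 by 1.49. The heat shock list fell (12 lower and 4 higher of 18, median -0.44, adjusted p = 0.0161 with an estimated correlation), HSPA8 by 1.76 ± 0.0418. The p53 targets (12 higher and 1 lower of 21, median 0.24, adjusted p = 0.0143 with an estimated correlation) and apoptosis regulators (15 higher and 6 lower of 26, median 0.23, adjusted p = 0.0281) rose, with BBC3 at 2.52 ± 0.0983. These lists share BBC3, and the p53 list shares SESN2 with the ATF4 list. Apoptosis regulators hold genes for and against cell death, so their rise gives no direction. Autophagy and lysosome genes rose (19 of 26 higher and none lower, median 0.49, adjusted p = 0.00553 with an estimated correlation), and MAP1LC3B changed by 1.48 ± 0.0455. The AMPK and mTOR pathway list rose (13 of 17 higher and none lower, median 0.35, adjusted p = 0.0114 with an estimated correlation). Its members DDIT4 (REDD1) and EIF4EBP1 (4E-BP1), which both restrain mTORC1 output, changed by 1.78 ± 0.0434 and 2.35 ± 0.0763. This list shares DDIT4 and SESN2 with the ATF4 list, so the rises are not independent. It holds genes that act for and against mTOR, so its rise gives no direction of the pathway. Immediate early genes rose (18 higher and 3 lower of 25, median 0.65, adjusted p = 0.0239 with an estimated correlation), the zinc finger factor KLF6 by 1.64.

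Lipid and growth lists fell in Farage too. Of the 21 cholesterol synthesis genes 19 fell, 1 was not called and 1 rose (median -0.95, camera adjusted p = 2.0e-11, adjusted p = 0.00265 with an estimated correlation); adjusted over the list alone, 1 higher and 19 lower. ACAT2, which makes acetoacetyl-CoA at the start of the pathway, fell by 2.38 ± 0.0762 and overlaps TCP1 on the opposite strand, and SQLE fell by 1.08 ± 0.0322. The exception was LSS, which rose from 15.7 ± 0.783 to 25.8 ± 2.0 FPKM (0.68 ± 0.0632). Fatty acid synthesis fell (6 lower and 1 higher of 10, median -0.56, adjusted p = 0.0281 with an estimated correlation), SCD by 1.82 ± 0.0408 and FASN by 1.56 ± 0.0614. So did MYC and nucleolar targets (24 of 25 lower and none higher, median -0.63, adjusted p = 0.00436), G1/S and DNA replication (24 of 32 lower and none higher, median -0.48, adjusted p = 0.0143; adjusted over the list alone, 0 higher and 28 lower), oxidative phosphorylation (25 of 26 lower and none higher, median -0.56, adjusted p = 0.0239) and the proteasome (16 of 18 lower and none higher, median -0.41, adjusted p = 0.0281), each p with an estimated correlation. NOP16, a nucleolar gene that overlaps HIGD2A on the opposite strand, changed by -1.14 ± 0.0786. Cell cycle inhibitors and G1 regulators rose (8 higher and 2 lower of 15, median 0.35, adjusted p = 0.0457 with an estimated correlation). This list holds cyclin and cyclin-dependent kinase genes beside inhibitors, so its rise gives no direction for the cycle.

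In Farage the B cell receptor signalling list fell (16 lower and 3 higher of 22, median -0.50, adjusted p = 0.0239 with an estimated correlation), as did interferon-stimulated genes (12 lower and none higher of 17, median -0.44, adjusted p = 0.0281). MS4A1 fell from 356 ± 21.3 to 92.9 ± 7.69 FPKM (-1.93 ± 0.0853), and CD79B, PAX5 and CD22 fell by 0.80 ± 0.102, 0.63 ± 0.0617 and 0.30 ± 0.0727, whereas CD79A was at -0.06 ± 0.0645 (adjusted p = 0.536). Calls lost with the estimated correlation were those of metallothioneins (4 of 5 higher, median 1.22, adjusted p = 0.0572 with an estimated correlation), G2/M and mitosis (16 higher and 5 lower of 29, 0.18, adjusted p = 0.180), NF-kappaB targets (17 higher and 6 lower of 25, 0.33, adjusted p = 0.0872) and germinal centre B cell genes (12 lower and 5 higher of 19, -0.44, adjusted p = 0.0731). The last of these was also lost at the preset correlation in 5 of the 6 fits that left out a library (highest adjusted p = 0.119). NFKB2, which codes for an NF-kappaB subunit, rose by 1.36.

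Of the lists not called in Farage, SREBP2 regulation and sterol uptake had a median of 0.00 but a mean and a test direction below 0 (camera adjusted p = 0.337), with INSIG1 at -1.06 ± 0.0499 and SREBF2 at 0.09 ± 0.0471 (adjusted p = 0.176). Plasma cell differentiation had a median of -0.11 but a mean above 0 (adjusted p = 0.532), and ribosomal proteins a median of 0.01 but a mean below 0 (0.632). The other medians were 0.33 for LXR targets (adjusted p = 0.0934), 0.08 for fatty acid oxidation (0.425), 0.04 for NRF2 targets (0.545), 0.42 for xenobiotic receptor targets (0.254), -0.10 for glycolysis and hypoxia (0.503), -0.13 for antigen presentation (0.0971) and -0.01 for replication-dependent histones (0.552). Camera called 21 of 31 lists with the preset correlation (11 up, 10 down) and 17 with the estimated correlation (8 up, 9 down).

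The third comparison asks whether the lines responded alike. A shared part was seen: 3980 genes changed the same way in both lines, 2021 higher and 1959 lower, where independent lists of these lengths would share 966 and 805. By contrast, 748 genes changed in opposite ways, 300 of them higher in SU-DHL-8 and 448 higher in Farage, where 934 and 832 would be met by independent lists. Across the 17574 genes the fold changes of the lines correlated with Pearson r of 0.41 (jackknife SE 0.0242 over the 12 libraries) and Spearman rho of 0.40; genes are not independent replicates, so no p is given. Over the alternatives it ranged from 0.32 at a pseudocount of 0.1 to 0.53 for protein-coding genes alone.

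**Figure D2:**
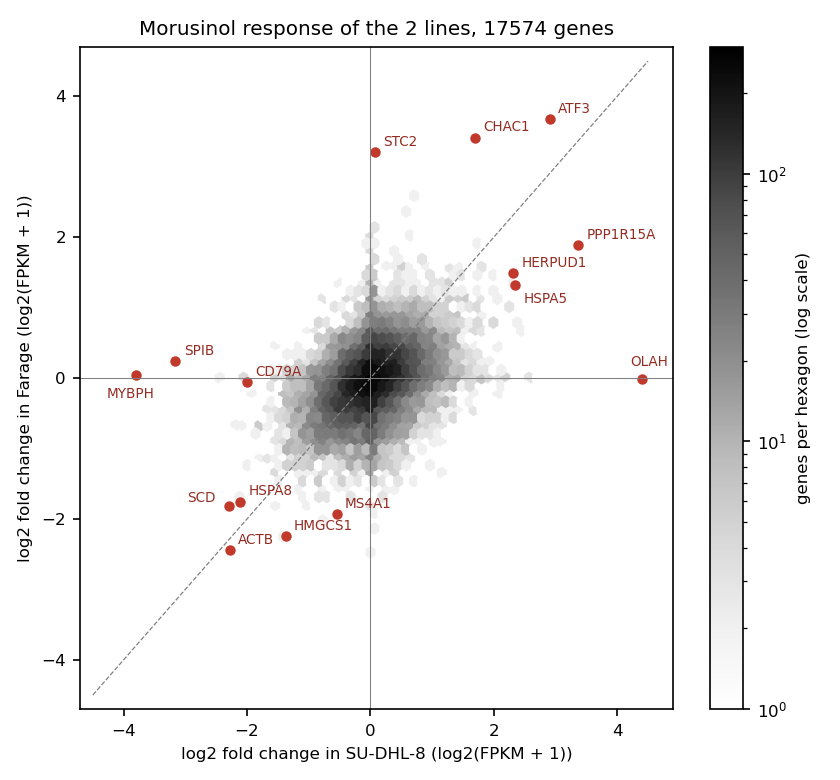
Log2 fold change (FPKM + 1) after morusinol in Farage against that in SU-DHL-8 for 17574 genes, shown as hexagons shaded by the number of genes on a log scale, with 15 named genes as red points and the line of equal change dashed. HSPA5 and HERPUD1 lie below the dashed line, ATF3 and CHAC1 above it, and CD79A fell in SU-DHL-8 with a value of -0.06 in Farage.

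The difference between the responses was tested directly, as the Farage response minus the SU-DHL-8 response, and 6126 genes were called (3038 above 0 and 3088 below), 1549 of which changed the same way in both lines. ATF4 targets rose more in Farage: 21 of 24 had a difference above 0 and 1 below (median 1.05, adjusted p = 0.0121 with an estimated correlation), with CHAC1 at 1.72 ± 0.158 and TRIB3 at 0.49 ± 0.0950. ER chaperones rose more in SU-DHL-8, with 13 of 20 below 0 and 1 above (median -0.54, adjusted p = 0.0121 with an estimated correlation), HSPA5 at -1.02 ± 0.0490; XBP1, at 0.54 ± 0.0641, went the other way. G1/S genes fell further in SU-DHL-8 (25 of 32 above 0, median 0.67). G2/M genes fell in SU-DHL-8 and had a median of 0.18 in Farage (adjusted p = 0.180 with an estimated correlation), and the difference was above 0 for 27 of 29 (median 0.83). Both lists had an adjusted p of 0.0121 for the difference with an estimated correlation. Their members were mostly lower in Farage controls than in SU-DHL-8 controls (medians -0.70 for G1/S and -0.63 for G2/M). Whether these starting levels account for the different responses was not tested. The mitotic genes BUB1B and TPX2 fell by 0.79 ± 0.0406 and 0.61 ± 0.0418 in SU-DHL-8 and rose by 0.42 ± 0.0406 and 0.50 ± 0.0418 in Farage, whereas the cyclin genes CCNA2, which overlaps EXOSC9 on the opposite strand, and CCNB1 fell in Farage as well (-0.44 ± 0.0512 and -0.26 ± 0.0430, against -1.15 ± 0.0512 and -1.44 ± 0.0430 in SU-DHL-8).

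The heat shock list fell more in SU-DHL-8 (median difference 0.50, adjusted p = 0.0121 with an estimated correlation), HSP90AA1 at 0.68 ± 0.0560. Differences above 0 were also called for NRF2 targets (0.63, 0.0138), cell cycle inhibitors and G1 regulators (0.53, 0.0121) and glycolysis and hypoxia (0.58, 0.0322), each as median and adjusted p with an estimated correlation. Interferon-stimulated genes had a difference below 0 (-0.54, adjusted p = 0.0272). These 9 of 31 lists held with the estimated correlation, against 21 with the preset correlation. Of the other 12, plasma cell differentiation had a median difference of -0.83 (adjusted p = 0.0527 with an estimated correlation), with CD38 at -1.96 ± 0.0877, and cholesterol synthesis -0.35 (0.121). At the B lymphocyte markers, the CD79A response differed between the lines ( 1.95 ± 0.0912, adjusted p = 3.2e-07), and MS4A1 fell more in Farage (-1.38 ± 0.121, adjusted p = 1.5e-05).

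Of the largest single differences, OLAH differed by -4.42 ± 0.105, MYBPH by 3.84 ± 0.117, PLEK by -3.31 ± 0.0750, SPIB by 3.40 ± 0.103 and TREML2 by -3.23 ± 0.114, and STC2 by 3.13 ± 0.120. OLAH was at 0.0172 and MYBPH at 0 FPKM in Farage controls and STC2 at 0.00445 FPKM in SU-DHL-8 controls, so for these 3 genes the difference shows in which line the transcript was made in quantity and does not compare folds. In the fit with precision weights, chosen after seeing the data, the STC2 difference was 0.65 (adjusted p = 0.633). That fit also has another offset near 0, so this change cannot be put down to precision. In Farage control and morusinol, PLEK was at 293 and 405, SPIB at 18.8 and 22.4 and TREML2 at 2.38 and 3.92 FPKM.

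**Figure D3:**
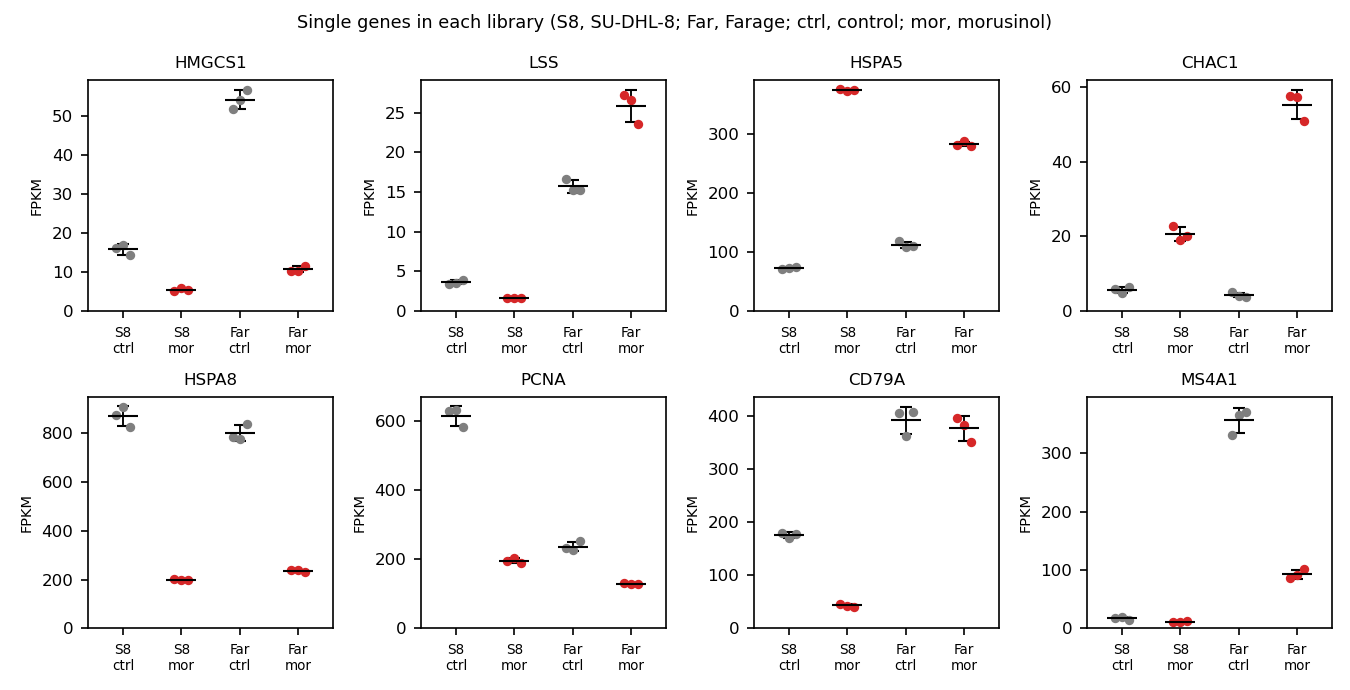
FPKM of 8 genes in each of the 12 libraries (points, grey for control and red for morusinol), with group means and SD (n = 3) as black lines. LSS fell in SU-DHL-8 from 3.64 to 1.65 FPKM and rose in Farage from 15.7 to 25.8 FPKM, while HMGCS1 fell in both lines.

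The lines differed widely before treatment. In Farage controls, compared with SU-DHL-8 controls, the detoxifying enzyme gene GSTP1 (8.39 ± 0.0684), the immunoglobulin heavy chain gene IGHM (8.01 ± 0.0609), the BCL2 relative BCL2A1 (7.42 ± 0.104), the deubiquitinase UCHL1 (7.05 ± 0.0590) and the transcription factor IRF8 (6.91 ± 0.0370) were higher, and each was at most 0.502 FPKM on average in SU-DHL-8 controls. The immunoglobulin lambda segments IGLV1-44 (-11.12 ± 0.112) and IGLC2 (-9.91 ± 0.0950) were lower, as was the MHC class II gene HLA-DRA (944 ± 45.5 to 0.207 ± 0.0119 FPKM from SU-DHL-8 to Farage). In all, 11271 genes (64.1%) were called, 6067 higher and 5204 lower in Farage. NF-kappaB targets were higher in Farage (all 25, median 2.31, adjusted p = 0.0124 with an estimated correlation), as were germinal centre B cell genes (16 of 19 higher and 3 lower, median 1.21, adjusted p = 0.0495). Camera called 13 lists here with the preset correlation (7 up, 6 down) and these 2 with the estimated correlation. Cholesterol synthesis genes had a median difference of 0.87 (16 higher, 3 lower, adjusted p = 0.0640 with an estimated correlation). The median was -0.70 for G1/S and DNA replication (27 of 32 lower, 2 higher) and -0.63 for G2/M and mitosis (25 of 29 lower, 3 higher). Each of these 2 lists also had an adjusted p of 0.0640 in camera with an estimated correlation.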

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

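Of the tests reported in this part, the regroupings of libraries and the summed olfactory receptor values were planned before their results were seen, and those on depth, scaling, the shift that genomic DNA allows, length and GC content, abundance, starting levels and precision were chosen only after. A response that differed between the lines, by the test of the difference itself (Farage minus SU-DHL-8), was found for 6126 of 17574 genes (34.9%). It was found for 72 of the 81 tested genes named in the text, many of which were chosen for large changes or differences. Of the lists, 21 of 31 were called with the preset correlation. Only 9 of these lists held with an estimated correlation. In 6 of 100 regroupings of the libraries 21 lists or more were called, but these keep the treatment effect of at least 1 line, whole or mirrored. On the log2 scale the difference was above 0 for MIR6813 (3.68), SPIB (3.40), RGS19 (2.64), GPT2 (2.36), CD79A (1.95), EIF4EBP1 (1.82), CHAC1 (1.72), LSS (1.49), SESN2 (1.48), DDIT4 (1.45), ATP2A3 (1.44), CTH (1.32), BUB1B (1.21), CCNB1 (1.17), TPX2 (1.11), CD22 (0.96), SLC7A11 (0.92), PCNA (0.78), BBC3 (0.78), ATF3 (0.78), MCM4 (0.77), DDIT3 (0.72), CCNA2 (0.71), VAV1 (0.70), HSP90AA1 (0.68), LDHA (0.58), XBP1 (0.54), PKM (0.53), TRIB3 (0.49), SCD (0.47), KLF6 (0.46) and HSPA8 (0.36). It was below 0 for PLEK (-3.31), TREML2 (-3.23), JCHAIN (-3.02), CD38 (-1.96), PPP1R15A (-1.48), MS4A1 (-1.38), RELB (-1.25), CD79B (-1.15), HSPA5 (-1.02), HMGCS1 (-0.87), HERPUD1 (-0.83), PAX5 (-0.81), IRF4 (-0.79), TNFRSF10B (-0.74), ACAT2 (-0.66), JUN (-0.61), MAP1LC3B (-0.55), RPL3 (-0.46), FASN (-0.30) and INSIG1 (-0.27). A further 5 differences turned direction under another setting: TSC22D3 (0.56, adjusted p = 6.7e-04; -0.44, adjusted p = 0.0370, at a pseudocount of 0.1 and -0.72, adjusted p = 0.0256, with precision weights), NAPSB (-1.25; 0.071 and 0.51 at these settings), INHBE (-0.61; 0.12 with precision weights), PTPN6 (0.35; -0.14 at a pseudocount of 3) and H2BC12 (-0.28; 0.052 with quantile normalization). The TSC22D3 difference was called in both directions, so its direction is not settled. The MIR6813 difference rests on values near 0 in Farage: 0.471, 1.44 and 0 FPKM in the control libraries and 2.12, 3.81 and 0 FPKM after morusinol. MIR6813 also lies within RGS19, so its difference is not independent of that gene. A further 15 genes were at 0 or under 1 FPKM on average in both groups of 1 line, so their differences depend on the pseudocount and compare no folds: OLAH (-4.42), TRAJ4 (-3.48), MMP8 (-3.28), CCL4 (-2.45), MPEG1 (-2.38), BCL2A1 (-1.06), GSTP1 (-0.70), IRF8 (-0.41), UCHL1 (0.40), IGHM (0.44), HLA-DRA (0.70), IGLV1-44 (1.46), IGLC2 (1.73), STC2 (3.13) and MYBPH (3.84). Of these, MPEG1 and GSTP1 turned with precision weights (0.17 and 0.13). The PTPN6 difference lost its call in 8 of the 12 fits that left out a library (adjusted p of 0.00618 to 0.0724), and that of FASN in 1 of them (without SU-DHL-8 control replicate 2, -0.27, adjusted p = 0.0511).

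Of the lists that held with the estimated correlation, the median difference of members was above 0 for ATF4 amino acid stress targets (1.05), G2/M and mitosis (0.83), G1/S and DNA replication (0.67), NRF2 oxidative stress targets (0.63), glycolysis and hypoxia (0.58), cell cycle inhibitors and G1 regulators (0.53) and heat shock response (0.50) and below 0 for ER chaperones and unfolded protein response (-0.54) and interferon-stimulated genes (-0.54). The calls of the other 12 were lost with it: those with a median above 0 were metallothioneins and metal response (1.09), xenobiotic receptor targets (0.51), autophagy and lysosome (0.30), apoptosis regulators (0.27), fatty acid oxidation (0.22) and proteasome subunits (0.21), and those below 0 were plasma cell differentiation (-0.83), cytosolic ribosomal proteins (-0.35), cholesterol synthesis (-0.35), NF-kappaB targets (-0.35), antigen presentation (-0.35) and replication-dependent histones (-0.28). At the preset correlation the call for NF-kappaB targets was lost without Farage control replicate 1 (-0.25, adjusted p = 0.0998) or 3 (-0.27, adjusted p = 0.0587), and that for fatty acid oxidation without Farage control replicate 2 (0.19, adjusted p = 0.0590).

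Regrouping the libraries gave a limited measure of chance, as the other splits keep a part of the difference between the groups. The 6 libraries of a line make only 10 splits, so the share can never fall under 0.1. The real split called 8216 genes in SU-DHL-8 and the highest other split 1; in Farage these were 7567 and 3, and for the controls 11271 and 0, with 1 of the 10 splits reaching the real count in each. For lists at the preset correlation the real and highest other counts were 22 and 19 in SU-DHL-8 and 21 and 16 in Farage. The other splits keep a part of the treatment effect: in Farage the ATF4 targets reached an absolute median of 0.77 in them, against 2.04. Their list calls, made with almost no called gene, can therefore not be read as false calls. With the estimated correlation every other split called 0 lists, against 15 and 17 for the real ones. The other splits leave treatment effect in the residuals from which the correlation is estimated, which can block calls. The 0 is therefore no measure of false calls. Regrouping treatment within each line, in 100 draws, gave a correlation as high as 0.41 in 1 draw, the real one (highest other 0.30). The treatment labels are thus not interchangeable, but these draws do not test whether unrelated responses would correlate as much. As many as 3980 genes changed the same way in 1 draw as well (highest other 748, in the draw that mirrors 1 line), but the remaining draws gave 0, as almost no gene was called in at least 1 line, so that count does not test whether the lines agree. As many genes with a different response were found in 2 of 100 draws, the real one among them. The other draw (9301 genes) is a structure of the samples. It mirrors the treatment labels in 1 line, which turns the difference of the responses into their sum. The count follows how much of the treatment effect a draw keeps: it was 3916 in a draw that kept SU-DHL-8 whole and mixed Farage. Equal responses would also call few genes in draws that mix both lines, so these draws cannot decide whether the responses differ. For the 21 lists with a different response, 6 of 100 draws gave as many (highest other 22), the real one among them. In each of the 6 at least 1 line kept its treatment contrast, whole or mirrored. Their list calls carry the treatment effect, so these draws cannot exclude chance and do not show it either. With the estimated correlation the real draw gave 9 lists, the mirrored draw 17 and each of the others at most 4. Draws that mix a line have the same limit as the splits, so these counts do not measure false calls.

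Non-coding genes moved apart in the lines: relative to 10507 protein-coding genes, the median log2 fold change of 2412 non-coding genes was 0.14 in SU-DHL-8 (0.09 to 0.16 with a library left out) and -0.13 in Farage (-0.15 to -0.07), which argues against lower depth of the treated libraries as the cause of both, since depth fell in both lines. One scaling factor per library would move genes of the same level alike, yet relative to coding genes of the same level the median in Farage was -0.16 (-0.18 to -0.12), which argues against scaling there. In SU-DHL-8 that median was only 0.026 (0.010 to 0.046), as scaling would give, so most of the change in this line goes with the level of the genes, and scaling stays open. Genomic DNA would add about the same FPKM to every gene, and the summed olfactory receptor values had a treated over control ratio of 2.87 in SU-DHL-8, a rise of only 0.0115 FPKM per gene, and of 1.03 in Farage, where 10 genes hold 71.3% of the control sum; with 2 SE these allow shifts of at most 0.019 and -0.028, which argues against it in both lines. Unspliced RNA, which was not tested, and a response of the lines stay open.

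Genes of oxidative phosphorylation, the proteasome and the heat shock response fell together, 58 of 62 members being below 0 in SU-DHL-8 (median -0.62) and 56 in Farage (-0.48). After the trend of the fold with transcript length and GC content over all coding genes was removed, the medians were -0.52 ± 0.0687 and -0.47 ± 0.0443 (bootstrap SD), which argues against that trend as the whole cause. After removing the trend with abundance they were -0.36 ± 0.0630 in SU-DHL-8, with 56 of 62 members still below 0, and -0.40 ± 0.0429 in Farage. Both lie more than 2 SD below the bound of -0.1. The bootstrap resamples members as if they were independent, though they are correlated (estimated at 0.17 for oxidative phosphorylation), so its SD can be too small. The size of the medians argues against abundance as the whole cause in either line, but the margin in SD is no test of it. In SU-DHL-8 a part of the fall goes with abundance, since the median before was -0.62. The effect of the treatment on these genes stays open in both lines.

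ER chaperones rose more in SU-DHL-8 and ATF4 targets more in Farage, with a gap of 1.60 between the median differences of the 2 lists. The values argue against unequal precision of the libraries, as the gap was 1.59 with precision weights and 1.55 to 1.62 with a library left out. For the 9 ATF4 targets whose control levels differed by at most 0.5 the median difference was 1.13 ± 0.297, against 1.05 over all members. Its size argues against starting levels as its whole source. For 10 such ER chaperone genes the median difference was -0.47 ± 0.139, within 2 SD of the bound of -0.2, so starting levels and the line cannot be told apart for these. Both are bootstrap SDs that treat members as independent, so they can be too small and no margin in SD is a test. A difference between the lines in how they meet stress stays open, as untested.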

How the results depend on the processing

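Precision weights, scaling to protein-coding genes and protein-coding genes alone were chosen after seeing the data, and the other alternatives before. Counts of called genes stayed within 1.5 times the reported ones except as follows. With a log2 fold change of at least 1, the counts were 1282 in SU-DHL-8, 888 in Farage, 1138 for the difference of the responses, 4274 for the controls and 235 for genes changed the same way, since fewer genes can pass. An adjusted p under 0.01 left 3928 genes with a different response, an FPKM of at least 5 left 7043 control differences because fewer genes were tested, and an estimated correlation left 9 lists with a different response. The correlation of the fold changes, 0.41, was 0.32 at a pseudocount of 0.1, 0.46 at 3, 0.37 without a filter, 0.51 with an FPKM of at least 5, 0.35 with precision weights and 0.53 for protein-coding genes alone; the cause was not tested.

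With a library left out, called genes ranged from 7268 to 7539 in SU-DHL-8, 6494 to 7041 in Farage, 5303 to 5871 for the difference of the responses, 10315 to 10734 for the controls and 3602 to 3802 for the same way in both lines. Each of these is below the count with all libraries. The correlation was 0.39 to 0.42, and called lists numbered 21 to 22, 19 to 20 and 19 to 21 for SU-DHL-8, Farage and their difference. A block for the replicate number called 7619 genes in SU-DHL-8 (7416 shared), 6853 in Farage (6600 shared) and 5110 for the difference (4895 shared). Residuals of control and treated libraries of the same number correlated at -0.079 to 0.033, and those of different numbers at -0.096 to 0.115. No shift shared by number was seen, which cannot tell whether the cultures were paired.

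Directions turned for the following values, and the cause was not tested. The difference between the lines became -0.44 for TSC22D3 and 0.071 for NAPSB at a pseudocount of 0.1, -0.14 for PTPN6 at 3, and 0.052 for H2BC12 with quantile normalization, which also took the FOSB control difference to -0.055. With precision weights it became 0.12 for INHBE, -0.72 for TSC22D3, 0.51 for NAPSB, 0.17 for MPEG1 and 0.13 for GSTP1. The fit with these weights also changed the offset near 0, the trend and the genes tested. TSC22D3, NAPSB, INHBE, MPEG1 and GSTP1 averaged at most 3.18 FPKM in the controls of at least 1 line. Among single genes, 7891 values kept direction and call over the alternatives other than left-out libraries, 149 lost a call and 84 gained one; for lists these were 1191, 60 and 11. Precision weights shared 7756, 7102 and 4911 calls with the fit as reported in SU-DHL-8, Farage and the difference, and 0, 0 and 20 genes were called with the opposite sign. Low values are limited by depth: at 6.05 M fragments in the shallowest library, 1 FPKM in a gene of 1 kilobase is about 6 fragments.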

Other observations

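The lists of aminoacyl-tRNA synthetases and of cytoskeleton genes, and all tests on them, were chosen after the data were seen. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, rose in Farage (13 of 20 higher and 5 lower, median log2 fold change 0.72, camera adjusted p = 6.2e-05, adjusted p = 0.0329 with an estimated correlation). In SU-DHL-8, 12 were higher and 4 lower (median 0.18, adjusted p = 0.0135), and this call was lost with an estimated correlation (adjusted p = 0.151). The difference between the lines had a median of 0.33 (adjusted p = 3.9e-05, adjusted p = 0.0504 with an estimated correlation). The synthetases may therefore be regulated with the ATF4 targets, as a hypothesis: the values it needs were met with the preset correlation, by a median as low as 0.18 in SU-DHL-8, and only in Farage with the estimated one.

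Of 29 tested actin and tubulin cytoskeleton genes, 26 were lower and none higher in SU-DHL-8 (median log2 fold change -0.63, camera adjusted p = 8.8e-14, adjusted p = 0.00747 with an estimated correlation). In Farage 24 were lower and 2 higher (median -0.64, adjusted p = 6.8e-12, adjusted p = 0.0117 with an estimated correlation). ACTB, which prompted the list and is 1 of its members, is not independent evidence of its direction. After the trend of the fold with abundance over all coding genes was removed, the medians were -0.48 ± 0.151 (bootstrap SD) in SU-DHL-8 and -0.51 ± 0.122 in Farage. Their size argues against that trend as the whole cause. The SD treats the members as independent, so it can be too small. ACTB, often used as a reference gene, had log2 fold changes of -2.28 ± 0.0440 and -2.45 ± 0.0440.

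Of 771 lincRNA genes tested, 240 rose and 34 fell in SU-DHL-8, whereas 82 rose and 122 fell in Farage. Of 1322 antisense genes, 294 rose and 71 fell in SU-DHL-8, against 98 and 215 in Farage, and of 1563 processed pseudogenes, 188 rose and 126 fell, against 56 and 232. Pseudogene values rest on fragments that their parent genes can share. Transcripts of the 7SL genes, which lack a poly(A) tail, were measured as well and held 2.31% to 4.53% of the estimated fragments. The replication-dependent histone gene H2BC12 was at 1273 to 1828 FPKM on average over the groups. Whether its transcripts carried a tail was not tested, so its level does not tell which kind of RNA was captured.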
